A study of Arabidopsis thaliana with 6 samples.

How the data were processed

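Seedlings of Arabidopsis thaliana were taken at 15 days from agar plates (0.8%) that held sucrose at 20 g/L. The temperature was 22 °C and the lights were on for 23 h a day, per the labels' protocols. RNA was sequenced from 2 libraries of L119, a transgenic line that served as the wild type, and from 2 libraries of the sams3 mutant. Bisulfite sequencing was done on 1 library of each genotype, and those libraries were not analysed here.

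The values used are log2 fold changes and p-values from the authors' comparison of the RNA libraries, sams3 over L119, in 3 lists deposited by the authors. Per the file headers, the authors kept features that changed at least 2-fold with a p-value below 0.0001. Whether the p-value was adjusted is not given in the sources used here. The submitters' processing notes name Bismark, Bowtie2 and edgeR and the build TAIR10, without versions or settings. A further table, headed as transposable elements (TEs), was byte for byte the same as the list of up-regulated genes and was not used, so TEs that rose were not analysed here. No per-library values or standard errors were used, the sequencing depth is unknown, and no list of all genes tested by the authors was used. A gene outside the lists is therefore called not listed, never unchanged.

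Symbols, gene types and gene order came from the RefSeq table of assembly TAIR10.1, in which 1335 of the 1336 listed gene identifiers were found. Its name differs from the authors' build, so no coordinates are printed and the planned test by distance to the centromeres was not run. In its place, the share of loci of type pseudogene was taken among the 10 neighbours on each side, and a share of at least 30% was called a pseudogene-rich neighbourhood. Both gene identifiers in the TE list have that type in the table.

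Without a background of tested genes, no enrichment against the genome was computed. Each gene group was tested by the split of its listed members into higher and lower against the split of all other listed genes, with Fisher's exact test, two-sided, and Benjamini-Hochberg (BH) adjustment within each family. The families were the 16 gene lists fixed before the data were examined (14 with a listed member), InterPro domains named in the deposited descriptions with at least 6 listed genes (115 domains), and biological process terms with at least 8 (31 terms). A list of 36 jasmonate genes was written after values had been seen, including those of 7 of its members. Domain, process and neighbourhood tests were also chosen after the lists had been looked at. Terms for location and tissue in the descriptions were looked at too and are not reported. Process terms were read from 605 genes, and 28 descriptions that give only a number of processes were left out. Shares of listed genes have exact (Clopper-Pearson) 95% intervals, which cover counting error only. The directions of neighbouring listed loci were compared with 100000 permutations of the directions over the listed genes.

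Named genes were those with the 10 largest folds and the 5 smallest p-values in each direction, SAMS3, examples with large folds from each fixed list, and the 5 TEs with the largest falls. The rule's minimum expression level for the largest folds could not be applied to lists without levels. Members of domains and of the jasmonate list were named after their values had been seen.

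The set tests were checked on simulated directions drawn over the real genes. With directions shuffled gene by gene, 3 of 200 draws gave a domain past an adjusted p of 0.05 and 0 of 200 gave a fixed list. The shuffling removed the shared direction of adjacent loci, so these rates do not hold for sets of neighbouring genes. Most fixed lists were also too small to pass at any split. Sets of at least 8 genes with all members made lower were recovered in 400 of 400 cases for domains and 200 of 200 for fixed lists. For fixed lists every case was the cold, drought and abscisic acid list, the only list of that size. All-lower sets this large pass almost by construction, so the recovery says nothing about partial leanings or smaller lists. Sets made higher were not simulated. They are harder to detect, since most listed genes were higher. Alternatives tried were stricter thresholds on p and fold, neighbouring members counted once, other windows and other minimum sizes. Counting once was applied to members of the tested set only, and the comparison genes kept all their neighbours. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.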

Results

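The transcriptomes of sams3 seedlings, which carry a mutation in S-adenosylmethionine synthetase 3, and of L119 seedlings, the transgenic line used as wild type, were compared to ask which genes and TEs change when this enzyme of methyl donor synthesis is affected. Each genotype had 2 RNA libraries from whole seedlings. The labels do not say that they came from separate cultures, so the authors' p-values measure the spread between these libraries, which may be technical.

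More genes rose than fell in sams3. The authors' deposited table lists 894 genes as higher and 442 as lower, so 66.9% of the 1336 listed genes were higher (exact 95% interval 64.3 to 69.4%). Rises were also larger: the median absolute log2 fold change in the authors' deposited table was 1.62 for higher genes and 1.27 for lower genes. Among the 346 genes with an absolute log2 of at least 2, 83.2% were higher, and of the 65 with at least 5, 61 were higher and 4 lower. SAMS3 (AT3G17390) itself is in neither list, which gives no value for its transcript and does not check the labels.

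**Figure D1:**
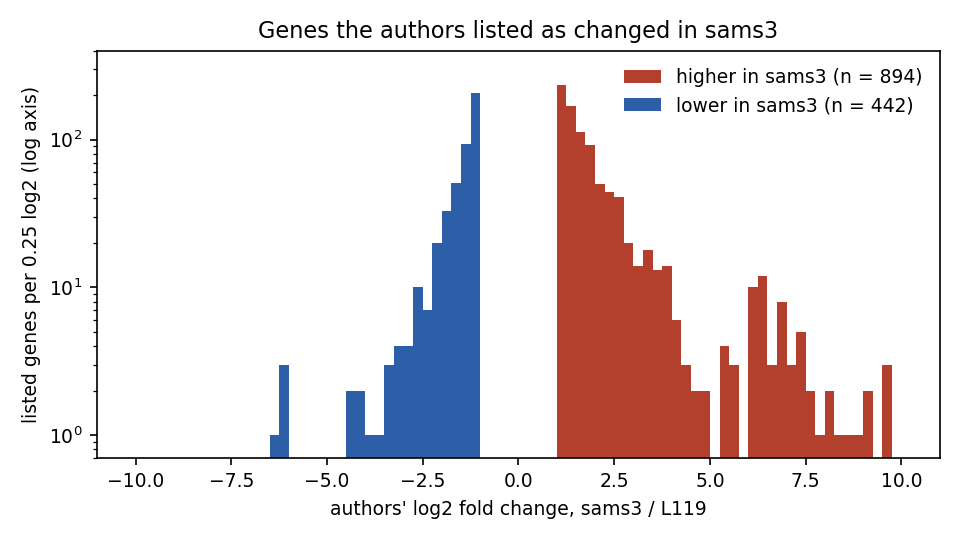
Number of genes per 0.25 log2 step (log axis) against the log2 fold change of sams3 over L119 in the authors' deposited table, for 894 higher and 442 lower genes. The higher genes extend to 9.74, while the lower genes end at -6.28.

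Genes with the largest rises were mostly unnamed loci, among them noncoding RNAs and pseudogenes. In the authors' deposited table, log2 fold changes were 9.74 for AT1G24996, 9.66 for the transcribed pseudogene AT4G06748, and 9.51 and 9.09 for the noncoding RNAs AT2G15555 and AT2G01422. At a similar fold, the p-value in the authors' deposited table was 1.29e-12 for AT1G24996 and 1.78e-44 for AT4G06748. The same deposited table by the authors gives 9.07 for AT2G40955, 8.82 for AT5G45570, a Ulp1 protease family gene, 8.51 for AT5G41830, 8.36 for AT4G08093, 8.13 for AT4G18540 and 8.02 for AT4G07940. The smallest p-values among higher genes were listed as 0 in the authors' deposited table, for 7 genes. The 5 of these with the largest folds were NATA1 (log2 4.53 in the authors' deposited table), an ornithine acetyltransferase, the trypsin inhibitor TI1 (4.14), the lipid transfer family gene AT4G22470 (3.99), CORI3 (3.01), which is induced by coronatine, and PR4 (2.80). The other two were NIT2 (2.62 in the authors' deposited table) and EARLI1 (2.59).

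Genes with the largest falls were of mixed kinds. In the authors' deposited table, log2 values were -6.28 for SAG12, a senescence-associated cysteine protease, -6.22 for PCR1, a cadmium resistance gene, -6.19 for the MADS-box gene AT4G36590 and -6.11 for the ankyrin repeat gene AT3G54070. Next in the authors' deposited table came LpxC3 (-4.33), LpxC2 (-4.30), the heat shock factor HSFA6A (-4.23), MYB76 (-4.04), AT2G20870 (-3.76) and the floral identity gene AP1 (-3.70). LpxC2 and LpxC3 are similar copies, so their single values are uncertain. The smallest p-values among lower genes in the authors' deposited table were those of ERF104 (log2 -2.09), AT5G44680 (-2.01), a DNA glycosylase family gene, AT5G19190 (-2.10), AT3G22235 (-2.07) and NCED4 (-1.92). A fold this large in a gene near 0 in a genotype depends on the authors' prior count. Of the 30 genes named by fold or p, 5 (SAG12, AT4G36590, AT3G54070, LpxC2 and LpxC3) had p-values above 1.32e-06, the threshold that a Bonferroni correction over all 37899 reference loci gives.

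Listed members of the fixed list for cold, drought and abscisic acid response leaned to falls, a call that was lost with neighbouring members counted once (adjusted p = 0.233, Fisher's exact test). Of 20 fixed members, 8 were lower, 1 was higher and 11 were not listed, against a list-wide majority of rises (Fisher's exact test, two-sided, p = 0.000878, BH-adjusted p = 0.0123 over 14 lists). The largest fall among these members in the authors' deposited table was that of CBF2, a transcription factor of the cold response (p = 6.32e-125). Log2 values in the authors' deposited table were -1.83 for CBF3, of the same family, and -1.92 for RD29B and -1.34 for RAB18, markers of abscisic acid and dehydration. LTI30, a dehydrin, was the member that rose (1.32 in the authors' deposited table). CBF1, CBF2 and CBF3 are neighbours with similar sequences, as are COR15A and COR15B. Listed genes annotated in the deposited descriptions with a response to cold numbered 6 higher and 4 lower (Fisher's exact test, adjusted p = 0.662), and those for water deprivation 5 higher and 4 lower (adjusted p = 0.487). Neither set passed, against 26.8% lower among all genes with such terms.

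None of the other 13 lists with a listed member passed an adjusted p of 0.05, by the same Fisher's exact test. For 11 of them no split of so few listed members could have passed, so their p-values do not count against a shared direction. Heat shock and salicylic acid genes, the other two, could have passed only by falling. Of the 15 flowering genes, 3 fell and 0 rose (p = 0.0360, adjusted p = 0.252), with log2 values in the authors' deposited table of -3.70 for AP1, -2.16 for FUL and -1.51 for SOC1. Of the 11 heat shock genes, 5 rose and 0 fell (adjusted p = 0.497), among them HSP17.6A at 2.73, HSP17.4 at 2.70 and HSFA2 at 1.68 in the authors' deposited table. Among 13 sulphur genes, 4 rose and 0 fell (adjusted p = 0.579), led in the authors' deposited table by BGLU28 (1.92) and GGCT2;1 (1.67), both markers of sulphur deficiency. Seed markers also had 4 rises and 0 falls of 15 (adjusted p = 0.579), with the seed storage genes SESA3 at 7.40, SESA2 at 2.60 and SESA1 at 2.37 in the authors' deposited table. These SESA genes are near-identical neighbours, so their single values are uncertain.

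Defence genes linked to salicylic acid went both ways, with 5 of 24 higher and 2 lower (adjusted p = 1). In the authors' deposited table, PDF1.2a rose by 1.95, EDS5 by 1.72, WRKY18 by 1.69 and PR1 by 1.33, whereas NIMIN1 was at -1.73 and WRKY70 at -1.04. PDF1.2a is known as a marker of jasmonate and ethylene rather than of salicylic acid. Ethylene genes had 3 rises of 15 and 0 falls (adjusted p = 0.704), with ACS7, an enzyme that makes the ethylene precursor from S-adenosylmethionine, at 2.91 and ERF1 at 1.98 in the authors' deposited table. Glucosinolate genes split 2 to 2 of 22 (adjusted p = 0.704), and the regulators MYB76 (-4.04) and MYB29 (-1.73) were lower and CYP83B1 (1.02) and MAM3 (1.01) higher in the authors' deposited table. Phenylpropanoid genes had 3 rises of 25 and 0 falls (adjusted p = 0.704), with TT8 at 1.45 and F5H at 1.39 in the authors' deposited table. For iron, NAS3 (1.71) and NAS2 (-1.73) were the listed members of 16 in the authors' deposited table (adjusted p = 0.704).

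Few genes of the pathway that SAMS3 belongs to were listed. Of 30 genes of the methionine and S-adenosylmethionine cycle, 2 were listed and both fell (adjusted p = 0.383), the homocysteine methyltransferase gene HMT3 (-1.19) and the S-adenosylmethionine decarboxylase gene BUD2 (-1.03) in the authors' deposited table. Of 32 genes of DNA methylation and silencing, 0 were listed, as were 0 of 12 root markers. In the fixed list of 7 loci taken as silenced by DNA methylation, 2 rose and 1 fell (Fisher's exact test, adjusted p = 1). Rises were those of SDC (2.38) and QQS (2.27), and the fall that of PHE1 (-3.17) in the authors' deposited table. PHE1 is an imprinted gene and not a plain case of such silencing, so its fall does not count against these rises. Photosynthesis had 2 falls of 26 (adjusted p = 0.383), LHCB2.1 (-1.12) and LHCB2.2 (-1.10) in the authors' deposited table, which are near-identical copies. PRR9 was the listed member of the 12 clock genes, at -2.61 in the authors' deposited table (adjusted p = 0.579).

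**Figure D2:**
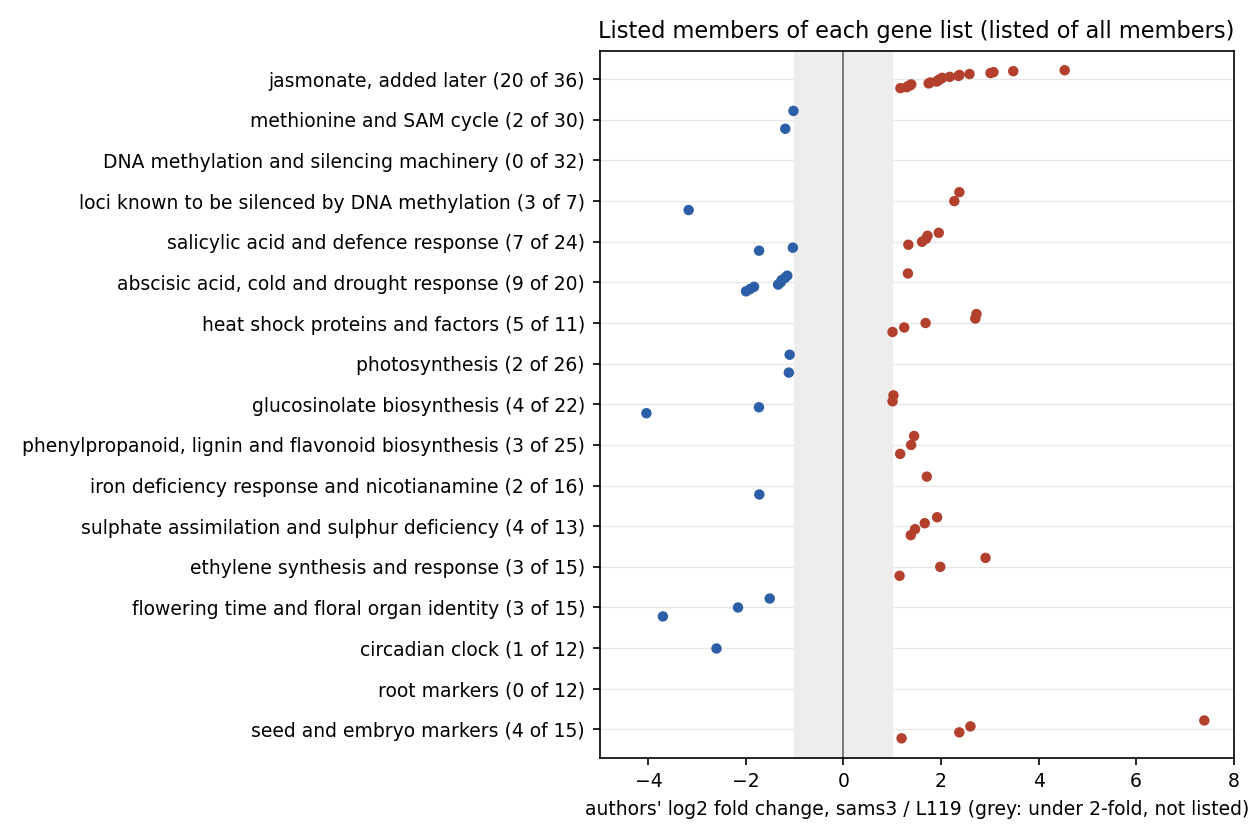
Log2 fold change of sams3 over L119 in the authors' deposited table for each listed member of the 16 fixed lists and of the jasmonate list, which was added later. Each point is a gene, the numbers are listed members of all members, and the grey band marks changes under 2-fold, which the lists leave out. In the cold and drought row 8 of 9 points lie below 0, and in the jasmonate row 20 of 20 lie above.

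TEs that fell numbered 30 in the authors' deposited table, 28 with TE identifiers and 2 with gene identifiers, with a median absolute log2 of 1.55. The authors' deposited table gives the largest falls as -7.33 for AT3TE44395, -6.65 for AT2TE20905, -6.07 for AT5TE93075, -4.00 for AT4TE21055 and -3.79 for AT4TE21100. Of the 30, 18 had p-values below the Bonferroni threshold over reference loci. Reads from related copies of a TE cannot be told apart in such a list, and without TEs that rose no balance of directions can be given.

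Among the changed genes themselves, 0 higher and 0 lower genes had the reference type that the table uses for TE genes. The authors placed gene identifiers of that type in the TE list, so this 0 may be fixed by how the lists were built. Transcribed pseudogenes are a separate type in the reference and numbered 19 higher and 6 lower. Noncoding RNAs numbered 14 and 1, and long noncoding RNAs 3 and 1. These splits by type were not tested. Pseudogene-rich neighbourhoods held 4.93% of the 893 placed higher genes and 3.39% of the 442 lower genes, a difference that did not pass the test (Fisher's exact test, two-sided, p = 0.257). With an absolute log2 of at least 2 the shares were 10.8% and 3.45%, which did not pass either (Fisher's exact test, two-sided, p = 0.0908). Within the higher genes the share differed between classes of size of the rise. It was 34.4% of the 61 genes with a log2 of at least 5 and 2.15% of the 605 with a log2 under 2 (Fisher's exact test, two-sided, p = 1.82e-15). These sizes were chosen after the values had been seen. At an absolute log2 of 3 to 5 the share was 5.56% of 72 higher and 15.4% of 13 lower genes. Rises this large can come from counts near 0 in L119. Some of the large rises had nearly the same size in the authors' deposited table. Log2 values were 6.187 for MYB21, AT3G59620 and AT1G36675 and 6.186 for AT5G26970. Such ties go with counts near 0 in L119 for these genes, where the fold depends on the prior count. The other large rises were not sorted in this way. For the class as a whole, the size of a rise and a low level in L119 cannot be told apart without expression levels.

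**Figure D3:**
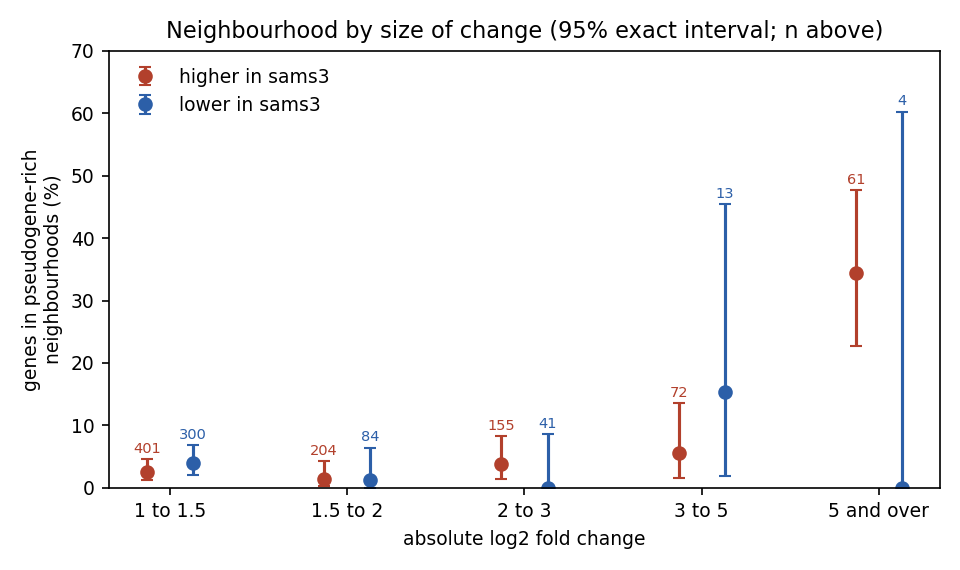
Share of genes in pseudogene-rich neighbourhoods (at least 30% of the 20 nearest loci) by absolute log2 fold change, for higher and lower genes, with exact 95% intervals and the number of genes above each point. Among higher genes the share is 2.49% in the smallest size class and 34.4% in the largest, where the lower genes number 4.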

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

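The thresholds on p of 0.01 and 0.001, the count of each identifier once and the removal of TE genes took away no listed gene, and the count of TE genes was 0 from the start, so these 20 alternatives could change nothing and say nothing about stability. Tests with a Bonferroni threshold, with neighbouring members counted once and with other windows or minimum sizes were chosen after the data were seen. Of the other 41 alternatives, 29 left the result on its side of the threshold or within its range, and 0 reversed one. With an absolute log2 of at least 2, higher genes numbered 288, lower genes 58 and lower TEs 13, the share higher was 83.2%, and 0 fixed lists and 0 domains passed. Under that setting 10 jasmonate genes were left, all higher (Fisher's exact p = 0.224). Fewer genes were tested there by construction. The Bonferroni threshold left 18 lower TEs, 790 higher and 362 lower genes. With neighbouring members counted once, 13 domains, 2 process terms and 0 fixed lists passed, the last because the cold and drought list kept 6 members of which 16.7% were higher. The difference in pseudogene-rich share between higher and lower genes, 1.53 percentage points, ranged from 0.875 with a share of at least 50% to 7.32 with an absolute log2 of at least 2, and did not pass in any setting. The range of the difference in neighbourhood share between large and small rises was 23.4 to 36.4 percentage points over its alternatives. No paired analysis was possible because no per-library values were used, and for that reason filters on low values, another normalization or tool, another pseudocount and leaving out each replicate were not run. The windows of 2 Mb and 5 Mb and all alternatives for TEs that rose were not run either. The depth of the libraries is unknown.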

Other observations

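The tests in this part were chosen after the lists had been looked at, except those of lower neighbours and of the SAMS3 segment, which were set before their values were seen. Jasmonate genes of a list put together by hand leaned to rises. Of 36 members of the list written after values were seen, 20 were higher, 0 lower and 16 not listed (Fisher's exact test, two-sided, p = 0.000438). MYC4, a transcription factor of jasmonate signalling, is outside this list and fell (log2 -1.03 in the authors' deposited table). The count of 0 lower therefore depends on which genes were put in the list. With an absolute log2 of at least 2 the call was lost, with 10 higher and 0 lower (Fisher's exact test, p = 0.224). In the authors' deposited table the biosynthesis genes AOC1 (2.58), OPR3 (2.18), LOX4 (1.96) and LOX2 (1.78) rose, as did the repressor genes JAZ10 (3.48) and JAZ8 (2.35) and CYP94C1 (3.07), which inactivates the hormone. Without the 7 members whose values had been seen first, 13 were higher and 0 lower (Fisher's exact test, two-sided, p = 0.00671). This is not free of the earlier look, since the whole list was written after it. The test also treats genes of a shared response as independent. Sets taken from the deposited descriptions had no lower gene, yet at their size even such a split could not pass the exact test, so they decide nothing: response to jasmonic acid stimulus had 9 higher and 0 lower genes (p = 0.122, adjusted p = 0.315), and the Tify domain of JAZ proteins 6 and 0 (p = 0.185 before adjustment).

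By Fisher's exact test, 23 of 115 domains had a split of higher and lower genes that passed a BH-adjusted p of 0.05, many of them sharing genes, and with an absolute log2 of at least 2, 0 passed. Since most listed genes were higher, falls were easier to detect: an all-lower domain passed with 6 genes, whereas all-higher domains of up to 12 genes did not and the smallest that passed had 14. The 16 of 23 that leaned to lower genes therefore give no balance of directions. With neighbouring members counted once, 13 of the 23 still passed, all 13 leaning to lower genes, so that each call of a domain leaning to higher genes was lost. Since the comparison genes were not counted once, this loss is no even comparison of the directions. The smallest p-values were those of the C3HC4 RING finger, with 3 higher and 14 lower genes (adjusted p = 0.00308), and the homeodomain-like fold, with 10 and 20 (adjusted p = 0.00579). Protein kinase-like domains had 63 higher and 11 lower genes (adjusted p = 0.0138), a call that was lost at 49 and 11 with neighbours counted once (adjusted p = 0.0893, Fisher's exact test). They include in the authors' deposited table the peptide receptors PEPR1 (1.24) and PEPR2 (1.25), the receptor EFR (1.04) and the cysteine-rich kinase CRK13 (2.65). MADS-box genes had 1 higher (AGL15) and 8 lower (adjusted p = 0.0138, and 0.0166 with neighbours counted once). Listed genes with an NPH3 domain numbered 7, all lower (adjusted p = 0.0134), and those with a B-box 6, all lower (adjusted p = 0.0140), with RPT2 at -1.21, COL2 at -1.31 and BBX14 at -1.24 in the authors' deposited table. RPT2 acts in phototropism, and B-box genes are known in light signalling. Among process terms, 4 of 31 passed: transcription regulation that is DNA-dependent had 7 higher and 16 lower genes (adjusted p = 0.000468), regulation of transcription 21 and 21 (adjusted p = 0.00950) and cell redox homeostasis 2 and 6 (adjusted p = 0.0451), each with more lower genes than the rest. Protein phosphorylation leaned the other way, with 52 and 5 (adjusted p = 0.00950). With neighbours counted once both transcription terms passed, while phosphorylation (43 and 5, adjusted p = 0.0631) and redox homeostasis (2 and 4, adjusted p = 0.176) did not.

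Directly adjacent listed loci shared a direction in 109 of 121 pairs, against 55.7% by chance (permutation p = 1e-05, the smallest that the permutations can give). For listed loci 2 to 5 loci apart the count was 132 of 215 (permutation p = 0.0494). Overlapping genes and similar neighbouring copies are among the adjacent pairs. Under a normal approximation, 107 of the 203 genes with an absolute log2 under 1.1 in the authors' deposited table had p-values below 2.45e-14, the smallest that a coefficient of variation of 0.1 between 2 and 2 libraries allows.

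The genes with the largest rises lay in pseudogene-rich neighbourhoods more often than those with small rises. A lower listed gene lay within 10 loci of 10 of the 61 genes with a log2 of at least 5 (upper bound 28.1%). That is under the 50% set beforehand, and of the 21 in pseudogene-rich neighbourhoods 0 had one. This cannot decide whether reads were exchanged between copies. A copy further away, one that fell less than 2-fold, or one that the authors put in the TE list would not be counted. Within 300 loci of SAMS3 lay 0 of the 61 (upper bound 5.87%) and 0 of the 21. That argues against a linked segment of this width as the source of most of these rises. A wider segment was not looked at. Of these 21 genes, 15 had p-values in the authors' deposited table below the Bonferroni threshold. That argues against chance in read counts near 0 for these 15 and leaves it open for the other 6. Chance differences between the seedling samples stay open for all 21, since the spread between these libraries may be technical. A difference in depth, or counts from a single library, stays open. A loss of silencing in sams3 may contribute, as a hypothesis that needs the methylation of these loci, which was not analysed here.

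The rises in the jasmonate list could come from more flower tissue in the sams3 samples, and the lists cannot decide it. AP1 fell by 3.70 on the log2 scale in the authors' deposited table, and of the 15 flowering genes 3 fell, 0 rose and 12 were not listed. SEP4, a floral MADS-box gene outside that list and named after its value was seen, fell as well (-1.26 in the authors' deposited table). The falls argue against more tissue that expresses AP1, FUL, SOC1 and SEP4. The 12 genes that were not listed say nothing about other flower tissue. MYB21 (6.19) and MYB24 (6.41), genes of late flowers that jasmonate also induces, rose in the authors' deposited table, with p-values of 2.15e-05 and 5.54e-05. Both p-values lie above the Bonferroni threshold of 1.32e-06. GRP19 (6.62, p = 3.68e-76) and GRP20 (3.95, p = 1.34e-41), neighbouring genes of anther oleosins named after their values were seen, rose as well in the authors' deposited table, which goes with more flower tissue. Wounding at harvest stays open too, with 13 higher and 0 lower genes annotated with a response to wounding (Fisher's exact test, adjusted p = 0.0960), as does an effect of the mutation.

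The falls in the fixed cold list and among listed B-box genes could reflect harvest at another time of day, although annotated light response genes, with 5 higher and 7 lower, did not pass (Fisher's exact test, adjusted p = 0.0878). Only 1 of the 12 clock genes, PRR9 (-2.61 in the authors' deposited table), was listed, and no listed evening gene of the clock allows the opposite movement to be looked for. RVE1 (-1.68), which follows the clock, fell as well in the authors' deposited table. Harvest time and genotype therefore cannot be told apart for these genes.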
